A study of Mus musculus with 41 samples.

How the data were processed

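Blood plasma of mice on a C57BL/6 background was the source of all 41 small RNA libraries, per the sample labels. The design text of the series describes 41 human plasma samples instead, 26 with the disease and 15 controls. The sample labels were followed, and the tables list mouse miRNA names. RNA was isolated with the miRNeasy Serum/Plasma kit and libraries were made with Illumina small RNA kits, per the labels' protocols. FastQC 0.11.7, cutadapt 1.14, R 3.4 and DESeq2 are named in the submitters' processing notes, with no version for DESeq2 and no statement of which step each served. The aligner, genome build and miRNA reference release are not given in the sources used here.

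Each deposited table lists, per the file headers, mature miRNAs by precursor with a read count, a read count adjusted for multiple mapping (an estimated count in which each read is divided over the places it maps to), and the same value as RPM, scaled to all reads of the library. The counts carry no normalization by the authors. The RPM column, computed by the authors before deposit, was used only to recover the total reads of each library. A mature miRNA with several precursors appears once per precursor, so the largest read count was taken per mature name. The library size was the sum of the adjusted counts. Those 2 choices were made after the tables were seen and before any model was fitted. The tables list counts of 2 or more, and a miRNA missing from a table was taken as 0. Of 1265 mature names, 500 passed edgeR's filterByExpr by genotype with a minimum count of 10; they held 99.99% of the miRNA reads. The other 765 were not tested, mmu-miR-1a-3p among them. Reads shared between near-identical miRNAs are counted at each, so mmu-miR-486a-5p and mmu-miR-486b-5p, or mmu-miR-669a-5p and mmu-miR-669p-5p, cannot be separated.

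Samples were grouped by the genotype labels: 15 WT, 7 Ccm1+/-, 7 Ccm3+/-, 7 Ccm1-/- and 5 Ccm3-/-. The library number and the sample sheet position in the titles gave 6 batches, called A, B1, B2, C1, C2 and D; B1 and B2 form library number block B, and C1 and C2 form block C. No label states a batch, so these are inferred. Heterozygotes lie in A, B1 and B2 with 7 WT libraries, homozygotes in C1, C2 and D with 8. Ccm3-/- is present in C1, with 2 libraries, and in C2, with 3. No 2 libraries of the 820 pairs held identical values; the highest correlation of log2 values between 2 libraries was 0.995.

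A quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) with a term for batch and a term for genotype was fitted to all 41 libraries, with TMM normalization and 31 residual degrees of freedom. The common dispersion was 0.180. Each genotype was compared with WT. The mean of the 4 genotype effects was tested as CCM against WT. Ccm3 was compared with Ccm1 at each zygosity, and the mean homozygous effect with the mean heterozygous effect. All tests are 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are given with their standard error (SE, the log2 fold change divided by the square root of the F statistic). Levels are TMM-scaled CPM relative to the miRNA reads of a library, given as mean and standard deviation (SD) over libraries. The TMM factors can carry the CPM of mmu-miR-486a-5p above the nominal total.

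There were 14 lists of miRNAs: erythrocyte, platelet, leukocyte, endothelial, smooth muscle and pericyte, brain, liver, striated muscle, epithelial miR-200, let-7 family, miR-17 clusters, miR-30 family, the imprinted Dlk1-Dio3 cluster and inflammation. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over all 112 pairs of a list and a comparison. Counts "adjusted over the list alone" re-adjust the edgeR p-values within a list. Some miRNAs stand in more than 1 list; the erythrocyte list shares 3 of its 9 members with others, the platelet list 3 of 8, the leukocyte list 3 of 8, the miR-17 clusters 3 of 13 and the inflammation list 4 of 9.

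The design, the lists, most alternatives and the rule for named miRNAs were fixed before the data were examined. The rule takes, per genotype against WT, the 12 risen and 12 fallen miRNAs with the lowest p among those past the threshold with the same sign in every batch that holds both groups. Where fewer than 10 pass, it adds the 10 with the lowest unadjusted p. In other comparisons it takes the 5 risen and 5 fallen with the lowest p past the threshold, or the 5 with the lowest p where none passes. It always takes mmu-miR-451a, mmu-miR-486a-5p, mmu-miR-16-5p, mmu-miR-126a-3p, mmu-miR-122-5p, mmu-miR-142a-3p, mmu-miR-9-5p, mmu-miR-124-3p and mmu-miR-1a-3p, and up to 4 members of each list that passed. Any other miRNA in the text was picked after its values were seen and is named there as such or as a list member.

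Alternatives were DESeq2 1.42.0, limma voom, other batch terms, RLE and library size scaling, other filters, an erythrocyte score as covariate, fits within single blocks or within the batches of a comparison, and each library left out in turn; for the lists, an estimated correlation and fry. The models were tested on simulated data at the real means and library sizes. Of 500 miRNAs, 100 were changed 2-fold and another 100 were changed 4-fold in the same simulation. With so many changed, the adjusted threshold is easier to pass, so the recovery may be overstated for comparisons with few changes. For Ccm1+/- edgeR recovered 51% of the 2-fold and 74% of the 4-fold changes; for Ccm3+/- 38% and 76%; for Ccm1-/- 58% and 93%; for Ccm3-/- 44% and 88%. Precursor coordinates were taken from GENCODE M21 (GRCm38), matched by name for 494 of the 500 tested miRNAs. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the plots.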

Results

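Circulating microRNAs (miRNAs) were measured by small RNA sequencing in plasma of mice modelling cerebral cavernous malformation (CCM). In this disease, clusters of dilated, leaky capillaries form in the brain; its familial form follows loss of function of Ccm1 (Krit1), Ccm2 or Ccm3 (Pdcd10). The 41 libraries comprised 15 WT, 7 Ccm1+/-, 7 Ccm3+/-, 7 Ccm1-/- and 5 Ccm3-/- samples, so that 26 carried the disease label. The labels do not say whether every sample came from a separate animal, so the spread between samples is the only replicate error available and can be partly technical. Small RNA libraries do not measure the Ccm1 and Ccm3 transcripts, so the genotype labels could not be checked on the targeted genes. The labels also do not say in which tissue or at what age the genes were inactivated in the homozygotes. Nor do they give the sex or age of the mice, so the balance of the groups in either could not be checked.

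Sequencing depth and miRNA content differed between the sets of batches. The libraries of batches A, B1 and B2, which hold all heterozygotes and 7 WT samples, had 518121 to 7939378 miRNA reads, and a median of 7.58% of their reads were miRNA. The libraries of C1, C2 and D, which hold all homozygotes and 8 WT samples, had 5120888 to 17909430 miRNA reads and a median miRNA share of 74.7%. They listed 587 to 812 miRNAs, against 299 to 592 in the first set. The red-cell miRNAs mmu-miR-486a-5p and mmu-miR-486b-5p together took 48.0% to 81.1% of the miRNA reads of a library, which leaves the remaining reads to all other miRNAs. Batch accounted for 92.0% of the variance of the first principal component, which held 25% of the total.

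**Figure D1:**
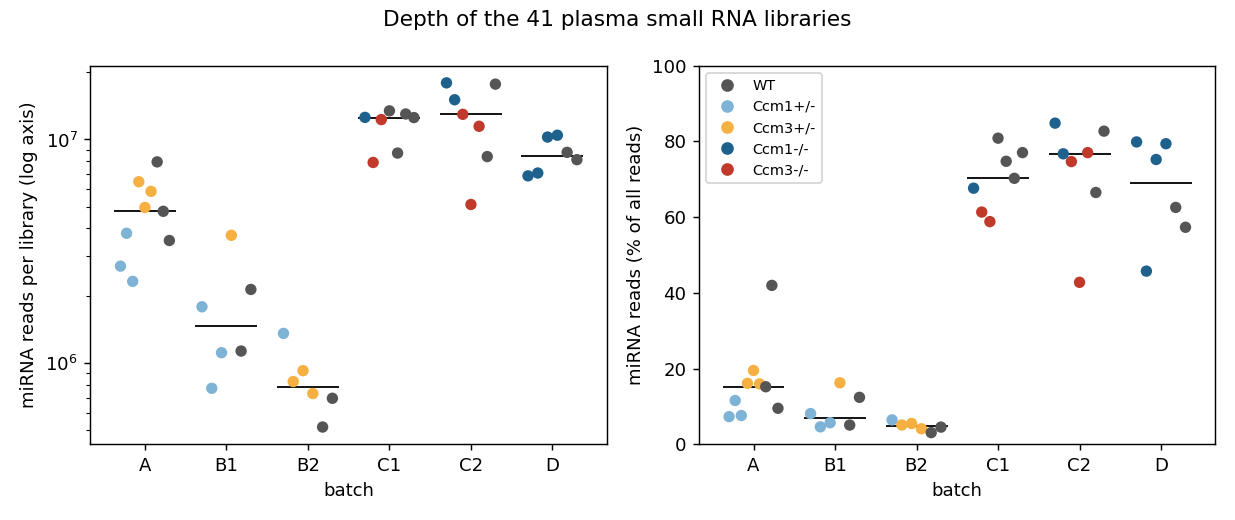
miRNA reads per library and the share of all reads that were miRNA, by batch, with genotype as colour; each point is 1 library, bars are batch medians and the read axis is logarithmic. The 21 libraries of batches A, B1 and B2 lie at or below 41.958% miRNA and the 20 libraries of C1, C2 and D at or above 42.768%.

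Plasma of Ccm1+/- mice was compared with WT plasma of the same batches to ask what loss of 1 Ccm1 copy changes. mmu-miR-8116, encoded in an intron of Ache (chromosome 5, 137293780 to 137293876), rose 3.89-fold (log2 1.96, SE 0.45, adjusted p = 0.0299), to 9.24 ± 3.68 CPM (SD, n = 7) from 2.33 ± 2.31 CPM in WT (n = 7), and lay above the WT mean of its batch in 6 of 7 libraries, with 6 to 53 reads per Ccm1+/- library and 0 to 11 per WT library. mmu-miR-211-5p, from an intron of the melanocyte gene Trpm1 (chromosome 7, 64205806 to 64205911), fell to 0.420 ± 0.549 CPM from 4.92 ± 5.15 CPM (adjusted p = 0.0299). Its CPM lay below the WT mean of its batch in 7 of 7 libraries, but the difference of mean log2 CPM had the same sign in only 2 of 3 batches. Its reads numbered 7 over all 7 Ccm1+/- libraries and 77 over the 7 WT libraries. These 2 were the only calls among 500 miRNAs, while 100 had an unadjusted p under the threshold.

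The erythrocyte list, miRNAs abundant in red blood cells, was lower in Ccm1+/- plasma by camera (adjusted p = 0.000468, median log2 fold change -0.81). The call was lost with an estimated correlation (adjusted p = 0.452). None of its 9 members passed over all miRNAs, and 5 fell when adjusted over the list alone. The values were -0.93 (SE 0.25, adjusted p = 0.0519) for mmu-miR-486a-5p, -0.94 (0.0519) for mmu-miR-486b-5p, -0.97 (0.0860) for mmu-miR-451a, a Dicer-independent miRNA of erythroid cells, -0.56 (0.224) for mmu-miR-16-5p and -0.63 (0.127) for mmu-miR-25-3p. mmu-miR-486a-5p and mmu-miR-451a lay below the WT mean of their batch in 7 of 7 libraries. The erythrocyte score, the mean log2 CPM of 3 of these miRNAs on library size scaling without TMM, was -0.34 (SE 0.19) against WT.

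Other miRNAs closest to the threshold did not pass: mmu-miR-486b-3p (-0.87), mmu-miR-425-3p (1.29) and mmu-miR-351-5p (1.49) at adjusted p = 0.0519, mmu-miR-8105 (-3.53, near the detection limit) at 0.0689, and mmu-miR-301b-3p (1.28) and mmu-miR-450a-5p (1.49) at 0.0724. The hepatocyte miRNA mmu-miR-122-5p stood at 0.67 (adjusted p = 0.430), the endothelial mmu-miR-126a-3p at 0.24 (0.565), the leukocyte mmu-miR-142a-3p at 0.14 (0.808), and the neuronal mmu-miR-124-3p and mmu-miR-9-5p at 0.51 (0.818) and 0.87 (0.565). Both calls missed the threshold, at log2 fold changes close to those above, with a batch term of 4 levels (1.85 and -3.46, adjusted p = 0.0621 for both) and with only the batches of the comparison (1.90 and -3.40, 0.0593 and 0.0770), as did mmu-miR-8116 with the erythrocyte score as covariate (1.81, 0.0705). In block A alone neither passed (2.25 and -2.91, adjusted p = 0.366 and 0.601), in block B mmu-miR-211-5p did (-3.68, 0.0331) and mmu-miR-8116 did not (1.60, 0.332). With single libraries left out, the count over all batches was 0 without WT 1, WT 4 or Ccm1+/- 2, 3 or 4 and 28 without Ccm1+/- 7. Scaling moved the split of calls from 1 higher and 1 lower to 2 and 3 with RLE factors and 96 and 5 with library size alone, where the median of all miRNAs shifted to 0.60, and the erythrocyte median to -0.17.

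Plasma of Ccm3+/- mice held 1 changed miRNA. mmu-miR-450a-5p, from an X-linked miRNA cluster (chromosome X, precursors at 53048154 to 53048244 and 53048299 to 53048367), rose 5.17-fold (log2 2.37, SE 0.43, adjusted p = 0.000931), to 4.99 ± 2.84 CPM (SD, n = 7) from 0.984 ± 1.26 CPM in WT (n = 7), and lay above the WT mean of its batch in 7 of 7 libraries. It had 2 to 65 reads per Ccm3+/- library and 0 to 7 per WT library, so that its level in WT lay at the limit of 2 listed reads. It passed in neither block alone, with a log2 fold change of 2.56 in block A (adjusted p = 0.413) and 2.59 in block B (0.265). mmu-miR-351-5p of the same cluster stood at 1.503 (SE 0.41, adjusted p = 0.114), and 85 miRNAs had an unadjusted p under the threshold.

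The erythrocyte list was lower in Ccm3+/- plasma as well (adjusted p = 0.0404, median log2 fold change -0.49; adjusted p = 0.808 with an estimated correlation). None of its 9 members passed over all miRNAs or adjusted over the list alone: mmu-miR-451a stood at -0.63 (adjusted p = 0.294), mmu-miR-486a-5p at -0.49 (0.284), mmu-miR-486b-5p at -0.49 (0.284) and mmu-miR-16-5p at -0.50 (0.311). With library size scaling the erythrocyte median was -0.16 and the call was lost (adjusted p = 0.0822), as it was without the batch term (0.106), with a batch term of 4 levels (0.0738) and at 10 CPM (0.0702). The Dlk1-Dio3 cluster, miRNAs of a maternally expressed imprinted domain, was also lower (adjusted p = 0.00785, median -0.40, 5 of 32 members above 0; adjusted p = 0.823 with an estimated correlation and 0.0614 at 10 CPM). No member passed. mmu-miR-411-5p stood at -1.07 (0.230), mmu-miR-668-3p at -1.85 (0.226) and mmu-miR-337-5p at -2.21 (0.230). The last lay near the detection limit, at no more than 1.28 CPM in Ccm3+/- and 2.65 CPM in WT. mmu-miR-329-3p was at 0 CPM in all 7 libraries and at 0.5 CPM or lower in WT.

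The platelet list missed the threshold (adjusted p = 0.0712, median 0.28) but was called higher with fry (0.0310), with no filter (0.0241) and with library size scaling (0.0299). Its member mmu-miR-191-5p stood at 0.84 (adjusted p = 0.157), above the WT mean in 7 of 7 libraries. mmu-miR-30c-5p stood at 1.03 (0.114), mmu-miR-669a-5p and mmu-miR-669p-5p at 1.05 (0.157), mmu-miR-8116 at 1.49 (0.157), mmu-miR-1955-5p at 2.27 (0.212) and mmu-miR-1843a-5p at 0.70 (0.212). mmu-miR-5134-3p had 0 CPM in all 7 Ccm3+/- and all 7 Ccm1+/- libraries, against 1.24 ± 2.10 CPM in WT (n = 7, adjusted p = 0.157 for Ccm3+/-). Only 4 of 7 Ccm3+/- libraries lay below the WT mean of their batch, and the log2 fold change was 0 in block A. mmu-miR-126a-3p (0.25, adjusted p = 0.612), mmu-miR-122-5p (0.59, 0.579), mmu-miR-142a-3p (-0.09, 0.889), mmu-miR-124-3p (0.39, 0.887) and mmu-miR-9-5p (-0.33, 0.871) did not pass. The call of mmu-miR-450a-5p was lost with only the batches of the comparison, at a log2 fold change of 2.32 (adjusted p = 0.125), and without the batch term, which brings in WT libraries at 7.75 ± 2.30 CPM (n = 8), its log2 fold change was 0.01. Library size scaling gave 6 higher and 0 lower calls, in place of 1 and 0.

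**Figure D2:**
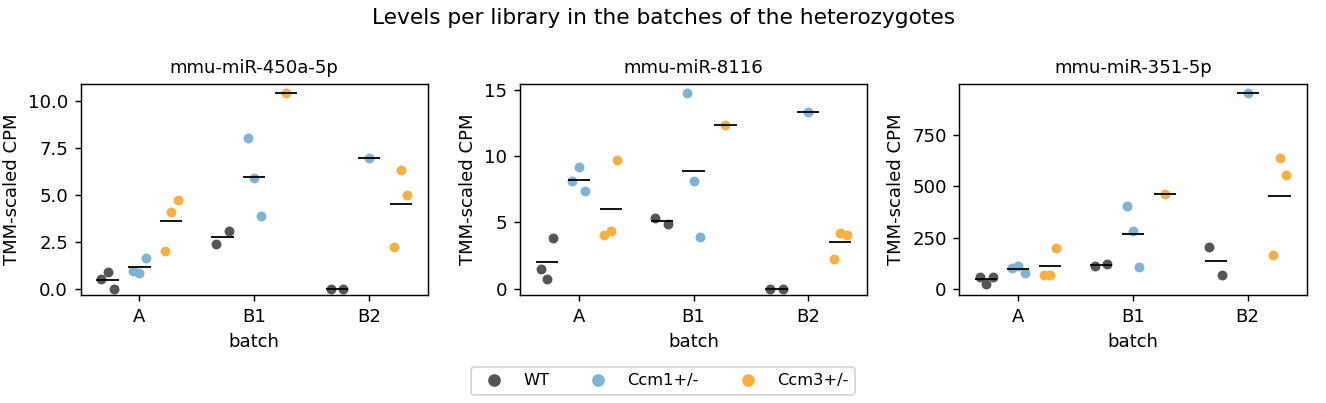
Levels (TMM-scaled CPM) of 2 X-linked miRNAs and mmu-miR-8116 in heterozygotes and WT by batch (A, B1, B2); each point is 1 library and bars are means within a batch. Over the 3 batches, mmu-miR-450a-5p averaged 4.99 CPM in Ccm3+/- and 0.984 CPM in WT.

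The heterozygous genotypes were compared with each other to ask whether loss of Ccm3 and loss of Ccm1 leave different miRNAs in plasma. No miRNA differed by edgeR, DESeq2 or voom, and 26 had an unadjusted p under the threshold. The lowest p-values belonged to mmu-miR-3963 (log2 4.05, adjusted p = 0.634), mmu-miR-27b-5p (1.89, 0.650), mmu-miR-8105 (3.20, 0.650), mmu-miR-6538 (1.91, 0.668) and mmu-miR-139-5p (0.62, 0.888). The liver list was lower in Ccm3+/- than in Ccm1+/- (adjusted p = 0.0367, median -0.34; adjusted p = 0.452 with an estimated correlation), with 0 of its 7 members past the threshold over all miRNAs or adjusted over the list alone. This call was lost without the batch term (adjusted p = 0.129), with a batch term of 4 levels (0.124), at 10 CPM (0.0914) and with the erythrocyte score as covariate (0.0559). mmu-miR-450a-5p stood at 0.88 (SE 0.37, adjusted p = 0.888) between them, so its call in Ccm3+/- alone was not shown to set the genotypes apart.

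Across miRNAs, the fold changes of Ccm1+/- and Ccm3+/- against their shared WT libraries had a covariance of 0.603 (r = 0.678). Simulated unchanged groups against the same WT libraries gave 0.245 (r = 0.534). Each miRNA was drawn independently there, so shifts shared by many miRNAs of a library are left out. Splitting the WT libraries between the genotypes gave 0.221 (r = 0.172), a value of the real heterozygotes without shared WT and not of unchanged groups. No call was shared between the genotypes, and 0.002 shared risen miRNAs would be expected of independent lists.

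In homozygous Ccm1-/- plasma 1 miRNA passed the threshold. mmu-miR-124-3p, an abundant miRNA of neurons, fell to 0.0625 ± 0.0786 CPM (SD, n = 7) from 3.77 ± 3.77 CPM in WT (n = 8; log2 -5.57, SE 1.23, adjusted p = 0.0233), below the WT mean of its batch in 7 of 7 libraries; it had 0 to 2 reads per Ccm1-/- library and 0 to 158 per WT library, with a WT median of 28.5. Its log2 fold change was -5.44 in block C, where it did not pass (adjusted p = 0.167), and -5.76 in block D (0.00884). The brain list, miRNAs enriched in neurons and glia, was lower (adjusted p = 1.22e-05, median -0.96; adjusted p = 0.419 with an estimated correlation). Of its 11 tested members 1 fell, or 3 adjusted over the list alone. At 10 CPM, where 6 members were tested, the brain median was -0.52 with 1 fallen (adjusted p = 0.00789). mmu-miR-9-5p stood at -2.63 (adjusted p = 0.322), mmu-miR-219a-2-3p at -2.67 (0.459) and mmu-miR-153-3p at -2.69 (0.597). All lay near the detection limit in Ccm1-/-, at no more than 1.71, 0.16 and 0.64 CPM. In WT their highest levels were 11.53, 0.59 and 1.63 CPM.

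The striated muscle list was higher in Ccm1-/- plasma (adjusted p = 0.000594, median 1.49; adjusted p = 0.419 with an estimated correlation). Without the batch term its median was 0.60 and the call was lost (adjusted p = 0.470), as it was with no filter (0.0580). None of its 3 tested members rose over all miRNAs and 3 did when adjusted over the list alone: mmu-miR-133a-3p at 1.42 (SE 0.52, adjusted p = 0.459) and mmu-miR-133b-3p at 1.49 (0.459) lay above the WT mean in 7 of 7 libraries, and mmu-miR-133a-5p at 1.53 (0.700) in 5 of 7. The Dlk1-Dio3 cluster was higher (adjusted p = 1.01e-10, median 0.63; adjusted p = 0.419 with an estimated correlation), with 30 of 32 members above 0 and none past the threshold. Its lowest p-values were those of mmu-miR-381-3p (0.99, adjusted p = 0.453), mmu-miR-431-5p (1.02, 0.459), mmu-miR-337-5p (1.23, 0.568) and mmu-miR-541-5p (0.77, 0.568). mmu-miR-127-5p, the other arm of the precursor of a list member and not itself in the list, stood at 1.24 (adjusted p = 0.453).

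mmu-miR-182-5p, of the miR-183 cluster, stood at 0.76 (SE 0.22, adjusted p = 0.244) in Ccm1-/- and mmu-miR-184-3p at 1.11 (0.392). The red-cell mmu-miR-451a (0.15), mmu-miR-16-5p (0.08) and mmu-miR-486a-5p (-0.03), the endothelial mmu-miR-126a-3p (-0.21), the hepatocyte mmu-miR-122-5p (0.16) and the leukocyte mmu-miR-142a-3p (-0.33) all had adjusted p-values of 0.980 or higher. In this comparison 27 miRNAs had an unadjusted p under the threshold. The call of mmu-miR-124-3p was lost with voom (log2 -3.86, adjusted p = 0.241). It also missed the threshold, at log2 fold changes close to the one above, with only the batches of the comparison (-5.67, adjusted p = 0.0938), a batch term of 4 levels (-5.53, 0.0732), no batch term (-5.19, 0.0541) or library size scaling (-5.57, 0.0571) and without the 2 libraries under 50% miRNA reads (-5.82, 0.0673), and leaving out any 1 Ccm1-/- library or WT 14 gave 0 calls.

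Ccm3-/- plasma held 81 changed miRNAs, 44 higher and 37 lower than in WT. mmu-miR-139-5p, from an intron of Pde2a (chromosome 7, 101475376 to 101475443), rose 2.48-fold (log2 1.31, SE 0.23, adjusted p = 0.000504), to 211.9 ± 41.2 CPM (SD, n = 5) from 89.8 ± 24.99 CPM in WT of its batches (n = 6), with every Ccm3-/- library above every WT library. mmu-miR-182-5p (chromosome 6, 30165918 to 30165992), of a cluster known for its role in sensory cells, rose 2.47-fold (1.31, SE 0.24, adjusted p = 0.000504), to 859.5 ± 324.3 CPM from 287.2 ± 109.3 CPM. mmu-miR-451a (chromosome 11, 78073170 to 78073241) fell 2.74-fold (log2 -1.45, SE 0.37, adjusted p = 0.00670), to 6865 ± 1824 CPM from 21980 ± 12800 CPM, below the WT mean of its batch in 5 of 5 libraries. mmu-let-7i-5p fell 2.19-fold (-1.13, SE 0.27, adjusted p = 0.00592), to 2577 ± 385 CPM from 6483 ± 3238 CPM.

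The Dlk1-Dio3 cluster (32 tested members, chromosome 12, plus strand, 109585789 to 109743795) was higher in Ccm3-/- plasma (adjusted p = 1.01e-10, median 1.43; adjusted p = 0.419 with an estimated correlation). All 32 members lay above 0 under each scaling tried; 15 rose, or 19 adjusted over the list alone, and with the erythrocyte score as covariate the median was 1.21 with 4 risen, with the brain score 0.97 with 0 risen. mmu-miR-410-3p rose 3.54-fold (1.82, SE 0.40, adjusted p = 0.00509), mmu-miR-541-5p by 1.51 on the log2 scale (0.00561), mmu-miR-434-3p by 1.72 (0.00630), mmu-miR-667-3p by 2.50 (0.00630) and mmu-miR-487b-3p by 2.74 (0.00630). Each lay above the WT mean of its batch in 5 of 5 libraries. The brain list moved with it without passing (adjusted p = 0.0823, median 1.88), but was called higher with no filter (0.00203). Of its 11 members 3 rose, or 5 adjusted over the list alone. Among them was mmu-miR-132-3p, which neuronal activity induces, at 0.98 (SE 0.23, adjusted p = 0.00592). mmu-miR-124-3p stood at 2.57 (0.0630) and mmu-miR-9-5p at 1.57 (0.184). The brain score, the mean log2 CPM of 5 brain miRNAs on library size scaling without TMM, was 2.04 (SE 0.78) against WT. In C1 the Dlk1-Dio3 median was 2.34 and the brain median 3.29; in C2 they were 0.39 and -0.11.

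**Figure D3:**
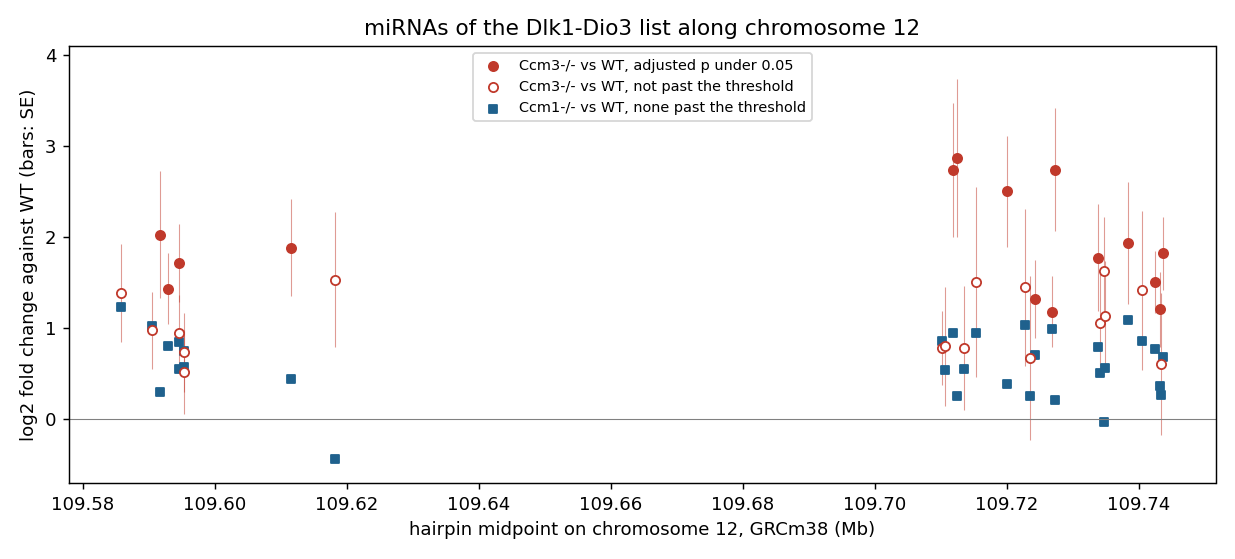
Log2 fold changes of the 32 tested Dlk1-Dio3 miRNAs along chromosome 12 (GRCm38 position) in Ccm1-/- and Ccm3-/- against WT; each point is 1 mature miRNA, bars are SE and filled red points passed the threshold. All 32 lie above 0 in Ccm3-/- and 30 of 32 in Ccm1-/-.

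The erythrocyte list was lower (adjusted p = 0.000474, median -0.64; adjusted p = 0.452 with an estimated correlation), and 4 of its 9 members fell, or 8 adjusted over the list alone. Besides mmu-miR-451a these were its cluster partners mmu-miR-144-5p (-1.88, SE 0.48, adjusted p = 0.00755) and mmu-miR-144-3p (-1.53, 0.0206), and mmu-miR-16-5p (-1.05, 0.0139). mmu-miR-486a-5p (-0.61, 0.125), mmu-miR-25-3p (-0.64, 0.0971) and mmu-miR-92a-3p (-0.46, 0.146) did not pass. The erythrocyte score, on library size scaling without TMM, was -0.60 (SE 0.21) against WT. The list call was lost without the batch term (median -0.35, adjusted p = 0.0531). Of the relatives of mmu-miR-16-5p, mmu-miR-15a-5p (-1.36), mmu-miR-15b-5p (-1.21) and mmu-miR-16-2-3p (-1.56) fell, with adjusted p of 0.00592, 0.00755 and 0.00592.

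The let-7 family, which restrains growth and represses Lin28, was lower (adjusted p = 0.0126, median -0.82; adjusted p = 0.771 with an estimated correlation): 4 of 9 members fell, or 6 adjusted over the list alone, with mmu-let-7f-5p at -1.33 (adjusted p = 0.00630), mmu-let-7a-5p at -0.82 (0.0129) and mmu-let-7d-5p at -0.97 (0.0236). With the erythrocyte score as covariate the let-7 median was -0.22, with 0 fallen and the call lost (adjusted p = 0.236), and the call was also lost at 10 CPM (0.0914). The miR-17 clusters, known for driving proliferation, were lower (adjusted p = 0.0404, median -0.55; adjusted p = 0.808 with an estimated correlation), with 2 of 12 members fallen over all miRNAs and adjusted over the list alone, mmu-miR-106b-5p (-1.25, 0.0187) and mmu-miR-93-5p (-0.95, 0.0182). The miR-17 median was -0.12 with the erythrocyte score as covariate, with 0 fallen (adjusted p = 0.768), and turned to 0.01 with library size scaling (0.0717); the call was also lost without the batch term (0.241) and at 10 CPM (0.0614). In the leukocyte list, 2 of 8 fell, the hematopoietic pair mmu-miR-142a-3p (2.61-fold, -1.38, adjusted p = 0.00592) and mmu-miR-142a-5p (-0.89, 0.00644). In the inflammation list, 2 of 9 rose, mmu-miR-132-3p and mmu-miR-212-3p (1.22, 0.00644), which share a locus (chromosome 11, 75173388 to 75173747). The platelet list had 1 of 8 fallen and the miR-30 family 1 of 8, mmu-miR-30e-5p (-0.89, 0.00769).

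The striated muscle list (median 1.44, adjusted p = 0.229) had 0 of 3 members past the threshold, or 2 adjusted over the list alone. The endothelial list had 0 of 10 (median 0.24, adjusted p = 0.694), with mmu-miR-126a-3p at 0.16 (0.727), and the hepatocyte mmu-miR-122-5p stood at -0.12 (0.900). Outside the lists, mmu-miR-193b-3p (1.45, adjusted p = 0.00375), mmu-miR-99b-5p (0.98, 0.00561) and mmu-miR-6395 (1.67, 0.00592) rose, and mmu-miR-181c-5p (-0.90, 0.00630) and mmu-miR-101b-3p (-1.17, 0.00769) fell. Across the 4 genotypes, 8 lists were not called by camera at the preset correlation in the TMM fit; their lowest adjusted p was 0.0712 for platelet (Ccm3+/-), 0.0929 for epithelial miR-200, 0.177 for smooth muscle and pericyte (both Ccm1-/-), 0.229 for leukocyte, 0.323 for miR-30 (both Ccm3+/-), 0.387 for liver (Ccm1+/-), 0.625 for inflammation (Ccm1-/-) and 0.694 for endothelial (Ccm3-/-). Of these, miR-30 was higher with library size scaling in Ccm1+/- (0.00706) and Ccm3+/- (0.0284), platelet was higher in Ccm1+/- with library size scaling (0.0223) and with no filter (0.0436), and leukocyte was lower in Ccm3-/- with the erythrocyte score as covariate (0.0151).

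**Figure D4:**
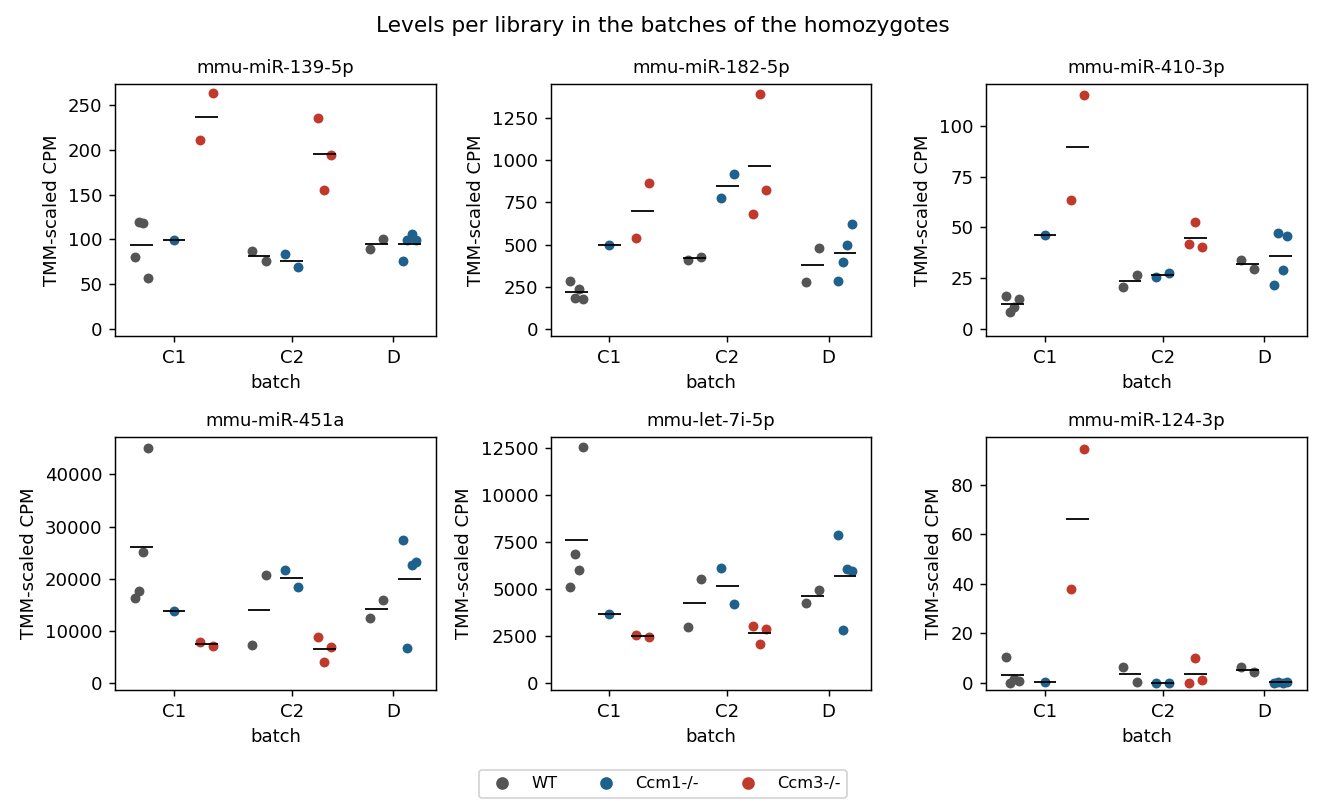
Levels (TMM-scaled CPM) of 6 miRNAs in homozygotes and WT by batch (C1, C2, D); each point is 1 library and bars are means within a batch. All 5 Ccm3-/- libraries lie at 154.88 CPM or higher for mmu-miR-139-5p, and the 6 WT libraries of C1 and C2 at 119.87 CPM or lower.

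Without the 2 Ccm3-/- libraries of C1, 1 of the 81 calls was left, mmu-miR-6395, and without the 3 of C2 58 passed, 46 of them among the 81. Leaving out Ccm3-/- 5 alone gave 20 calls, Ccm3-/- 3 gave 44, WT 13 gave 49 and WT 11 gave 51. For mmu-miR-139-5p the log2 fold change was 1.23 with the C2 libraries alone and 1.40 with the C1 libraries alone, for mmu-miR-182-5p 1.03 and 1.64, for mmu-miR-451a -1.33 and -1.54, for mmu-let-7i-5p -0.89 and -1.34, for mmu-miR-410-3p 1.13 and 2.56, and for the Dlk1-Dio3 median 0.55 and 2.15. Scaling moved the balance of directions from 44 higher and 37 lower with TMM. RLE factors gave 54 and 24, and library size alone gave 64 and 3. With library size the median of all miRNAs stood at 0.55 and the erythrocyte and let-7 medians at -0.09 and -0.28. A filter at 10 CPM in 5 libraries gave 51 higher and 13 lower, with an erythrocyte median of -0.30 and 2 of 9 members fallen. The balance turned the other way, to 21 higher and 46 lower, without the 2 libraries of C1, C2 and D under 50% miRNA reads.

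**Figure D5:**
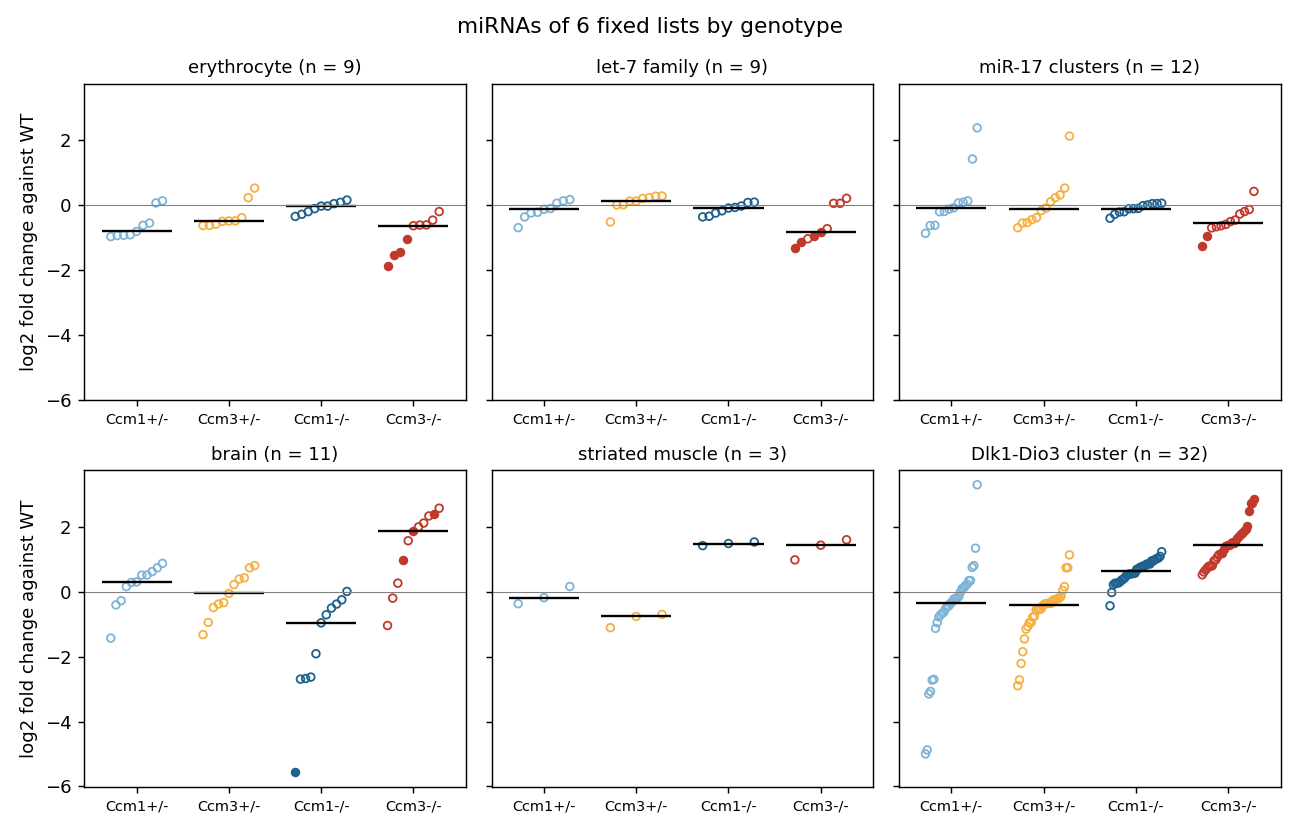
Log2 fold changes against WT of the members of 6 fixed lists in the 4 genotypes; each point is 1 miRNA, filled where its adjusted p passed the threshold, and bars are list medians. The Dlk1-Dio3 median is 0.63 in Ccm1-/- and 1.43 in Ccm3-/-, and all 9 erythrocyte members lie below 0 in Ccm3-/-, 7 of 9 with library size scaling.

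The homozygous genotypes differed from each other in 37 miRNAs, 17 higher and 20 lower in Ccm3-/- than in Ccm1-/-. Brain miRNAs were higher (adjusted p = 9.41e-06, median 3.35; adjusted p = 0.419 with an estimated correlation): 7 of 11 differed, or 8 adjusted over the list alone. The brain median was 1.80 with 2 higher with the erythrocyte score as covariate, and 1.87 at 10 CPM, where 6 members were tested and 4 were higher. mmu-miR-124-3p averaged 28.7 ± 39.9 CPM (SD, n = 5) in Ccm3-/- and 0.0625 ± 0.0786 CPM (n = 7) in Ccm1-/- (adjusted p = 0.000458), and the log2 difference was 4.20 (adjusted p = 0.0105) for mmu-miR-9-5p, 4.79 (0.0105) for mmu-miR-219a-2-3p and 5.32 (0.0201) for mmu-miR-344d-3p. mmu-miR-139-5p was 1.31 higher (SE 0.27, adjusted p = 0.00310; 90.6 ± 14.2 CPM in Ccm1-/-, n = 7).

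The erythrocyte list was lower in Ccm3-/- than in Ccm1-/- (adjusted p = 0.000468, median -0.68; adjusted p = 0.452 with an estimated correlation), with 3 of 9 members lower, or 5 adjusted over the list alone, and mmu-miR-451a at -1.61 (SE 0.40, adjusted p = 0.0201). The let-7 family was lower (adjusted p = 0.0345, median -0.70; adjusted p = 0.808 with an estimated correlation), with 1 of 9, or 6 adjusted over the list alone. The Dlk1-Dio3 cluster was higher (adjusted p = 0.000648, median 0.60; adjusted p = 0.808 with an estimated correlation), with 2 of 32. With the brain score as covariate the Dlk1-Dio3 median turned to -0.23, with 11 of 32 members above 0, the let-7 median to 0.15, with 8 of 9 above 0, and the erythrocyte median was -0.01. The erythrocyte median was -0.15 with library size scaling and -0.28 without the batch term, each with 1 of 9 members lower. With the erythrocyte score the let-7 median was -0.24 (adjusted p = 0.335). The let-7 call was also lost with RLE factors (0.0516), library size scaling (0.107) and at 10 CPM (0.178), the Dlk1-Dio3 call without the batch term (0.241) and at 10 CPM (0.184), and the erythrocyte call without the batch term (0.0733). Also lower were mmu-miR-15a-5p (-1.40, adjusted p = 0.0207), mmu-miR-195a-5p (-1.22), mmu-let-7i-5p (-1.05) and mmu-miR-16-2-3p (-1.46, 0.0279). Without the 2 Ccm3-/- libraries of C1 no miRNA differed, the brain median was 0.68 and the Dlk1-Dio3 median 0.03; with single libraries left out, 4 differed without Ccm1-/- 1, 5 without Ccm3-/- 5, 8 without Ccm3-/- 2 and 57 without Ccm1-/- 5. The split of 17 higher and 20 lower became 21 and 5 with RLE factors and 16 and 1 with library size. Without the 2 libraries of C1, C2 and D under 50% miRNA reads it became 7 and 24.

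Fold changes of Ccm1-/- and Ccm3-/- against WT had a covariance of 0.132 across miRNAs (r = 0.234). Simulated unchanged groups, with each miRNA drawn independently, gave 0.0867 (r = 0.329). The real homozygotes with the WT libraries split gave 0.11 (r = 0.170). No call was shared, with 0.074 shared fallen miRNAs expected of independent lists.

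Over all genotypes, the mean effect of CCM against WT changed 20 miRNAs, 3 higher and 17 lower. mmu-miR-450a-5p (0.99, SE 0.24, adjusted p = 0.0269), mmu-miR-1983 (1.28, 0.0317) and mmu-miR-182-5p (0.49, SE 0.13, adjusted p = 0.0401) rose. Such a mean can pass without a change in every genotype. mmu-miR-450a-5p stood at 1.49 in Ccm1+/- and 2.37 in Ccm3+/-, but at -0.07 in Ccm1-/- and 0.18 in Ccm3-/-. For mmu-miR-182-5p the values were 0.05 in Ccm1+/- and -0.16 in Ccm3+/-, against 0.76 in Ccm1-/- and 1.31 in Ccm3-/-. mmu-miR-451a (-0.73, SE 0.19, adjusted p = 0.0369), mmu-miR-486b-3p (-0.58, 0.0269), mmu-miR-16-2-3p (-0.76, 0.0317) and mmu-miR-15a-5p (-0.66, 0.0317) fell. mmu-miR-5134-3p (adjusted p = 0.0252) fell too. It was at 0 in all heterozygote libraries, but its WT libraries there held only 0 to 5.72 CPM. Its log2 fold change in Ccm3+/- was 0 in block A and -4.88 in block B, so block A shows no loss. The erythrocyte list was lower (adjusted p = 3.84e-06, median -0.52; adjusted p = 0.419 with an estimated correlation), with 5 of 9 members fallen, or 7 adjusted over the list alone. In Ccm1-/- the median of this list was -0.03, and mmu-miR-451a stood at 0.15. The calls for CCM against WT numbered 0 with the erythrocyte score as covariate or without the 2 Ccm3-/- libraries of C1. With single libraries left out they numbered 0 without WT 7, 1 without WT 6, WT 11, Ccm3-/- 5 or Ccm1-/- 2, and 36 without WT 10. The split of 3 higher and 17 lower became 5 and 5 with RLE factors and 43 and 1 with library size, where the erythrocyte median was -0.14.

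The homozygous and heterozygous effects, each against its own WT libraries, differed in 22 miRNAs, 7 with a higher homozygous effect and 15 with a lower one. The Dlk1-Dio3 cluster had the higher homozygous effect (adjusted p = 5.29e-10, median 1.41; adjusted p = 0.452 with an estimated correlation), with 4 of 32 members past the threshold, or 14 adjusted over the list alone; mmu-miR-337-5p differed by 3.76 and mmu-miR-541-5p by 1.59 (adjusted p = 0.0155). The value of mmu-miR-337-5p rests partly on levels near the detection limit, 0 to 1.28 CPM in Ccm3+/- and 0 to 2.65 CPM in WT. Its log2 fold change in Ccm3+/- was -5.33 in block A and -0.10 in block B. Outside the list, mmu-miR-127-5p differed by 2.82 (adjusted p = 0.0120). mmu-miR-182-5p and mmu-miR-183-5p, of 1 cluster, differed by 1.09 and 1.42. The homozygous effect was lower for mmu-miR-8116 (-2.42, adjusted p = 0.0120), mmu-miR-450a-5p (-1.87, 0.0179), mmu-miR-351-5p (-1.89, 0.0203), mmu-miR-330-5p (-2.15, 0.0179) and mmu-miR-181d-5p (-1.21). The striated muscle list had the higher homozygous effect (adjusted p = 0.0113, median 1.90; adjusted p = 0.452 with an estimated correlation), with 0 of 3 members past the threshold, or 3 adjusted over the list alone; without the batch term its median was 0.63 and the call was lost (adjusted p = 0.655), as it was at 10 CPM (0.0702). Across miRNAs, the effects of +/- and -/- had a correlation of -0.134 (SE 0.199) for Ccm1 and -0.0543 (SE 0.241) for Ccm3; miRNAs are not independent replicates. Scaling gave 13 higher and 15 lower with RLE factors and 2 and 10 with library size. With single libraries left out, 10 miRNAs (without Ccm3+/- 5) to 62 (without Ccm3+/- 4) differed. Without the batch term 193 miRNAs differed, and the differences turned to 0.76 for mmu-miR-450a-5p, 0.058 for mmu-miR-351-5p and -0.13 for mmu-miR-182-5p.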

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

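The test of the Dlk1-Dio3 cluster against the brain list, the fits with the miRNA share or the brain score as covariate, and the fits without the Ccm3-/- libraries of 1 batch were chosen only after the results they bear on were seen.

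The miRNAs that rose and fell in Ccm3-/- plasma were set against the share of red-cell RNA and the miRNA yield of the libraries. With the miRNA share of reads in the model, the median of the risen miRNAs was 1.55 (1.51 without it) and that of the fallen -1.07 (-1.05 without it), which speaks against yield as the whole cause of either. A fit without the 2 libraries of C1, C2 and D under 50% miRNA reads, Ccm3-/- 2 among them, was also chosen after the data were seen. It gave 21 higher and 46 lower calls, against 44 and 37, so a part for yield in the rise stays open. With the erythrocyte score in the model the risen kept a median of 1.20. The cut-off set beforehand was 0.757, which is 0.5 times the median without the score. By that rule red-cell RNA, as far as the score captures it, did not account for most of the rise. Of the 44, 10 still passed. The other calls ended with smaller estimates rather than larger errors (median SE of the 81 calls 0.372 before and 0.332 with the score). For 35 fallen miRNAs outside the score the median went from -1.04 to -0.51. The cut-off, 0.5 times the median of all fallen miRNAs, was -0.52. By that rule, and by a narrow margin, a smaller red-cell share may account for much of the fall. Yet library size scaling without the score also took the 37 fallen miRNAs to a median of -0.52, with 3 still past the threshold. The score itself differed from WT (-0.60, SE 0.21), so the fit cannot separate red-cell RNA from other effects of the genotype. The shrinkage therefore does not single out red-cell RNA. A change in what Ccm3-/- cells release was not tested apart from the red-cell share and stays open for both directions.

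Brain miRNAs lower in Ccm1-/- and higher in Ccm3-/-, and the Dlk1-Dio3 cluster higher in Ccm3-/-, were set against brain RNA in the plasma. The Dlk1-Dio3 median minus the brain median was 0.50 in C2 and -0.95 in C1. Resampling the list members, with the libraries held fixed, gave an SE of 0.36 and 0.97. This SE leaves out the spread between samples. Brain RNA and a change of the cluster itself therefore cannot be told apart with 3 and 2 Ccm3-/- libraries. With the brain score as covariate the Dlk1-Dio3 median in Ccm3-/- was 0.97, and 6 of the 44 risen miRNAs and 0 of the 37 fallen still passed, at medians of 1.06 and -0.69. Among WT libraries with batch means removed, 5 brain miRNAs correlated at a mean r of 0.47 (-0.21 to 0.83, 15 libraries), between the bounds of 0.5 and 0.2 set beforehand, so RNA that enters single samples at collection stays open beside a difference in brain RNA that follows the genotype, which was not tested. The high brain levels rest on 2 samples, Ccm3-/- 5 and Ccm3-/- 3, with mmu-miR-124-3p at 94.7 and 37.8 CPM.

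Calls in heterozygotes without the batch term, 78 in Ccm1+/- and 36 in Ccm3+/-, were set against the batches. The WT libraries of A, B1 and B2 differed from those of C1, C2 and D in 74 miRNAs, 31 higher and 43 lower in the first set, so a difference between batches is there to add calls. Of the 78 and 36 calls, 14 and 11 were also called between the WT sets with the same sign, so it may account for those. With the batch term in the model, 2 of the 78 and 0 of the 36 were still called. Whether batch differences too small to be called between the WT sets produced the others was not tested. No biological explanation was tested for this pattern.

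Other assignments of the samples within their batches were tried for each comparison. For the 81 calls in Ccm3-/-, 2 of 100 assignments, the real one included, gave as many. The other exchanged Ccm3-/- 1 and WT 10, both of batch C2, and gave 82. The share was 2 of 100 for CCM against WT (20 calls, highest other 20). It was 1 of 100 for the homozygous minus the heterozygous effect (22, highest other 4). For Ccm3-/- against Ccm1-/- it was 1 of 30 (37, highest other 4), the lowest share that 30 assignments allow. Such counts were rare among the assignments, but chance is not excluded, as the shares were not corrected for the number of comparisons. Without the 2 Ccm3-/- libraries of C1, the counts in the order given here were 1, 0, 13 and 0. Such counts were less rare for Ccm1+/- (2 calls, 11 of 100, highest other 29), Ccm3+/- (1, 12 of 100, highest other 10) and Ccm1-/- (1, 9 of 100, highest other 40), where chance may account for them. Ccm3+/- against Ccm1+/- had 0 calls, so every assignment gives at least as many (highest other 17) and the test cannot decide there. Counts several times the real one in single assignments may point to a structure of the samples beyond genotype and batch, which was not tested; the median of the other assignments was 0 in each comparison.

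By Dixon's test a single library stood far from its group in 8 of 74 groups tested. The rate of about 1 in 20 under chance holds for normally distributed values. CPM were not log-transformed here and batches were pooled, so an excess over chance cannot be read from this count. mmu-miR-122-5p was at 121.5 CPM in Ccm1+/- 2 (next 28.5) and 140.8 CPM in Ccm3+/- 2 (next 37.9). mmu-miR-142a-3p was at 417.8 CPM in Ccm1+/- 1 (next 224.2). Ccm3+/- 4 held 14930 CPM of mmu-miR-451a (next 6690), 38220 CPM of mmu-miR-16-5p (next 24610) and 34.8 CPM of mmu-miR-124-3p (next 5.02). mmu-miR-126a-3p was at 716.5 CPM in Ccm1-/- 5 (next 480.2), and mmu-miR-16-5p at 31050 CPM in Ccm3-/- 1 (next 24190).

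The effects of Ccm3-/- and Ccm1-/- differed, as log2 differences tested in the model, for mmu-miR-124-3p (8.14, a fitted value against a group near 0), mmu-miR-139-5p (1.31), mmu-miR-9-5p (4.20), mmu-miR-219a-2-3p (4.79), mmu-miR-344d-3p (5.32), mmu-miR-451a (-1.61), mmu-miR-15a-5p (-1.40), mmu-miR-195a-5p (-1.22), mmu-let-7i-5p (-1.05) and mmu-miR-16-2-3p (-1.46). The homozygous and heterozygous effects differed for mmu-miR-127-5p (2.82), mmu-miR-8116 (-2.42), mmu-miR-337-5p (3.76, near the detection limit in Ccm3+/-), mmu-miR-183-5p (1.42), mmu-miR-182-5p (1.09), mmu-miR-541-5p (1.59), mmu-miR-450a-5p (-1.87), mmu-miR-330-5p (-2.15), mmu-miR-181d-5p (-1.21) and mmu-miR-351-5p (-1.89).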

How the results depend on the processing

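The fits with multi-mapping adjusted counts, the miRNA share or the brain score as covariate, without the 2 libraries of C1, C2 and D under 50% miRNA reads, and without the Ccm3-/- libraries of C1 or C2 were chosen after the data were seen. No paired analysis was possible because the replicate numbers only name the samples in the order of the series and mark no shared animal, litter or day. Of the counts and other summaries, 85 alternative values stayed within 1.5 times the main value or its spread and 68 did not. The Ccm3-/- count stayed within that range in 14 of 17 settings, the Ccm1+/- count in 3 of 16. This compares totals only, not directions or which miRNAs were called. At 10 CPM in 5 libraries, Ccm3-/- had 64 calls, 51 higher and 13 lower, with 39 among the 81 of the main fit. That filter also leaves fewer miRNAs to test. With library size scaling, 64 were higher and 3 lower, with 47 among the 81. Where a count moved, the cause was not tested unless the setting itself leaves out samples or miRNAs. Of the values of single named miRNAs past the threshold, 778 stayed past it under other settings, 224 kept their direction without passing and 4 turned; of those not past it, 996 stayed so and 102 passed. The 21 libraries of the heterozygote batches had 518121 to 7939378 miRNA reads, so levels of a few CPM there rest on few reads, as for mmu-miR-450a-5p with 0 to 7 reads per WT library.

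DESeq2 gave 30 calls for Ccm1+/- (2 by edgeR), 12 for Ccm3+/- (1), 43 for CCM against WT (20) and 62 for the homozygous minus the heterozygous effect (22). voom gave 0 for Ccm1-/- (1) and 56 for the homozygous minus the heterozygous effect. Without the batch term the counts were 78 for Ccm1+/-, 36 for Ccm3+/-, 0 for Ccm1-/-, 21 for Ccm3-/- against Ccm1-/- (37) and 193 for the homozygous minus the heterozygous effect, and 3 values of that contrast turned: mmu-miR-182-5p to -0.13, mmu-miR-450a-5p to 0.76 and mmu-miR-351-5p to 0.058. A batch term of 4 levels gave 0 for Ccm1+/- and 0 for Ccm1-/-. RLE factors gave 5 for Ccm1+/- and 10 for CCM against WT. Library size scaling gave 101 for Ccm1+/-, 6 for Ccm3+/-, 0 for Ccm1-/-, 44 for CCM against WT, 17 for Ccm3-/- against Ccm1-/- and 12 for the homozygous minus the heterozygous effect.

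No filter gave 16 calls for Ccm1+/-, 3 for Ccm3+/-, 5 for Ccm1-/-, 2 for Ccm3+/- against Ccm1+/- (0) and 58 for Ccm3-/- against Ccm1-/-. A filter at 10 CPM in 5 libraries gave 23 for Ccm1+/-, 2 for Ccm3+/-, 7 for CCM against WT, 16 for Ccm3-/- against Ccm1-/- and 35 for the homozygous minus the heterozygous effect. The erythrocyte score as covariate gave 1 for Ccm1+/-, 17 for Ccm3-/- (81), 0 for CCM against WT, 5 for Ccm3-/- against Ccm1-/- and 51 for the homozygous minus the heterozygous effect. The brain score gave 2 for Ccm3+/-, 6 for Ccm3-/-, 0 for Ccm3-/- against Ccm1-/- and 45 for the homozygous minus the heterozygous effect, and turned mmu-miR-9-5p, itself part of the score, in Ccm3-/- against Ccm1-/- to -1.33. Multi-mapping adjusted counts gave 4 for Ccm1+/- and 14 for the homozygous minus the heterozygous effect. The miRNA share gave 4 for Ccm1+/-, 10 for CCM against WT and 24 for Ccm3-/- against Ccm1-/-.

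With only the batches of a comparison, Ccm3+/- and Ccm1-/- had 0 calls each. Block A gave 1 for Ccm1+/-, 0 for Ccm3+/- and 1 for Ccm3+/- against Ccm1+/-; block B gave 19 and 18 for Ccm1+/- and Ccm3+/-; block C gave 0 and block D 2 for Ccm1-/-. Without the 2 libraries under 50% miRNA reads, Ccm1+/- had 6 and Ccm1-/- 0. Without the Ccm3-/- libraries of C1 there were 1 for Ccm3-/-, 0 for CCM against WT, 0 for Ccm3-/- against Ccm1-/- and 13 for the homozygous minus the heterozygous effect; without those of C2 there were 23 for Ccm3-/- against Ccm1-/- and 11 for the homozygous minus the heterozygous effect.

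The lists gave 10 calls in the 4 genotypes at the preset correlation, 0 with an estimated correlation, 3 with fry (platelet up in Ccm3+/-, erythrocyte down and Dlk1-Dio3 up in Ccm3-/-), 6 without the batch term and 6 at 10 CPM. The correlation of the +/- and -/- effects of Ccm1 moved from -0.134 to -0.343 at 10 CPM. Shared calls of the heterozygotes moved from 0 to a mean of 0.1 with the WT libraries split.

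Leaving out 1 library gave 0 to 28 calls for Ccm1+/-: 0 without WT 1, WT 4 or Ccm1+/- 2, 3 or 4, 1 without Ccm1+/- 5, 4 without WT 3, 9 without WT 5 and 28 without Ccm1+/- 7. For Ccm3+/- the range was 1 to 3, with 2 without WT 3 or WT 6 and 3 without Ccm3+/- 4. For Ccm1-/- it was 0 to 2, with 0 without any Ccm1-/- library or WT 14 and 2 without WT 15. For Ccm3-/- it was 20 to 108, with 20 without Ccm3-/- 5, 44 without Ccm3-/- 3, 49 without WT 13 and 51 without WT 11. For CCM against WT it was 0 to 36, with 0 without WT 7, 1 without WT 6, WT 11, Ccm3-/- 5 or Ccm1-/- 2, 3 without Ccm3+/- 7 and 36 without WT 10. It was 5 to 13 without WT 1, 3, 12 or 13, Ccm1+/- 4 or 6, Ccm3+/- 2, 3, 5 or 6, Ccm3-/- 2 or 3, or Ccm1-/- 3. For Ccm3+/- against Ccm1+/- it was 0 to 0. For Ccm3-/- against Ccm1-/- it was 4 to 57, with 4 without Ccm1-/- 1, 5 without Ccm3-/- 5, 8 without Ccm3-/- 2, 13 without Ccm3-/- 3, 17 without Ccm1-/- 3 and 57 without Ccm1-/- 5. For the homozygous minus the heterozygous effect it was 10 to 62, with 10 without Ccm3+/- 5, 12 without WT 2, 5 or 9 or Ccm1-/- 2, 13 without Ccm1+/- 2, 14 without WT 10, 34 without WT 11, 35 without WT 7, 36 without Ccm1-/- 5, 40 without WT 3, 47 without Ccm1-/- 4, 50 without Ccm1+/- 7 and 62 without Ccm3+/- 4.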

Other observations

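The neighbours of single named miRNAs were looked up only after the results were seen; no other test belongs to this part.

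The X-linked cluster that holds mmu-miR-450a-5p also holds, among others, mmu-miR-351-5p (chromosome X, 53053255 to 53053353), mmu-miR-450b-5p, mmu-miR-322-5p, mmu-miR-503-5p and mmu-miR-542-3p. In Ccm3+/- plasma mmu-miR-322-5p stood at a log2 fold change of 0.83 (SE 0.31, adjusted p = 0.226) and mmu-miR-450b-5p at 0.81 (SE 0.42, adjusted p = 0.316). In Ccm1+/- plasma mmu-miR-503-5p stood at 2.21 (adjusted p = 0.127). The homozygous effect on mmu-miR-322-5p was lower than the heterozygous effect by a log2 difference of -1.28 (SE 0.37, adjusted p = 0.0364), with -0.85 (SE 0.33, adjusted p = 0.0692) in Ccm3-/- and -0.52 (SE 0.30, adjusted p = 0.909) in Ccm1-/-.

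mmu-miR-183-5p, encoded beside mmu-miR-182-5p (chromosome 6, 30169668 to 30169737), rose in Ccm3-/- plasma with a log2 fold change of 1.15 (SE 0.30, adjusted p = 0.00769). Of the brain list, mmu-miR-138-5p (1.88, SE 0.55, adjusted p = 0.0161) and mmu-miR-129-5p (2.40, SE 0.86, adjusted p = 0.0494) rose beside mmu-miR-132-3p, while the oligodendrocyte miRNAs mmu-miR-338-3p (0.27, adjusted p = 0.694) and mmu-miR-219a-5p (-1.04, adjusted p = 0.337) did not pass. In the platelet list, mmu-miR-26a-5p fell (-0.69, SE 0.23, adjusted p = 0.0339), while mmu-miR-223-3p (-0.29, adjusted p = 0.428) and mmu-miR-191-5p (-0.14, adjusted p = 0.793) did not pass.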
